A study of Danio rerio with 5 samples.

How the data were processed

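The series profiled where 2 FLAG-tagged zebrafish proteins, Drl (draculin) and Blf (bloody fingers), sat on the genome of blood progenitor cells. Both are zinc-finger proteins. Embryos lacking blf and 4 drl genes received mRNA for the tagged proteins, and RFP-positive cells were sorted at 20 hours post fertilisation. The assay was CUT&Tag, in which an antibody, here anti-FLAG, directs a transposase to cut and tag DNA beside the bound protein. Per the labels, 5 libraries were made, namely 2 for Drl-FLAG, 2 for Blf-FLAG and 1 input without antibody. The values of the input library were not analysed here, since only the 4 anti-FLAG libraries had a peak list. The labels differ on the mRNA. The genotype labels give 1 tagged mRNA per library and the design text speaks of separate injections, while the extraction protocol names both mRNAs without saying that they were separate. The groups follow the sample titles. If both had been injected together, anti-FLAG could not tell the 2 proteins apart.

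Per the submitters' processing notes, the tools were bcl2fastq, FastQC 0.11.9, Bowtie2 2.4.2, Picard 2.26.1, SAMtools 1.10, bedtools 2.30.0 and MACS2, with the build GRCz11. Settings, filters and the control used for peak calling are not given in the sources used here. The deposited lists were given 1 per anti-FLAG library, in the 10-column narrowPeak layout. The deposited values per peak were a display score, a fold enrichment at the summit, a −log10 p-value, a −log10 q-value and the summit position. The authors' score was 10 times the −log10 q-value, cut to a whole number, for all but 1 peak in each Drl-FLAG list and for every peak of the Blf-FLAG lists. The fold enrichment is the authors' own value and was used here only to describe and rank peaks within a list. Neither read totals nor coverage tracks were used here, so the depth had to be worked out from the peak values.

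Fold enrichment and p-value at a summit together fix the pileup and the background that MACS2 compared. They were inverted with its formulas, a Poisson upper tail and a fold with a pseudocount of 1. In each list the commonest background was taken as the genome-wide one. The step between pileups was then fitted, and each peak was assigned the whole number of fragments that matched its fold within 0.05%. Background coverage of a list was its genome-wide background divided by that step (0.803 and 0.802 for Drl-FLAG, 1 for Blf-FLAG), which undoes the scaling of the pileups. Between 99.4% and 99.8% of the peaks of a list were read back in this way. With a step 3% smaller, between 1.5% and 2.3% of 1000 sampled peaks matched. Peaks with a −log10 p-value over 290 were left unread, between 11 and 34 per list. The input of this step is a published formula, so the fragment counts are inferred values. On simulated peaks with a known step and background, 100% were read back. These peaks were made with the same formulas. They check the inversion and not whether the submitters' settings followed those formulas.

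Mitochondrial peaks were set aside. Peaks of the 4 lists that overlapped by at least 1 bp were joined into sites. A Drl site had a peak in both Drl-FLAG lists, and a Blf site in both Blf-FLAG lists. A Drl-only site had no peak in either Blf-FLAG list, and the reverse held for Blf-only sites. On simulated lists made with 1000 shared, 2500 Drl-only and 2000 Blf-only sites, the matching returned 1002, 2492 and 1989. Every simulated site was in both lists of its factor. The simulation therefore checks the joining of peaks and not the effect of missed peaks. The overlap expected by chance came from 100 random placements of one set on the same chromosomes. A local expectation came from 100 moves of each site by 20 to 100 kb. Chromosome lengths were taken as the end of the last peak in the 4 lists. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat sites as independent. Differences along the genome carry intervals from 1000 resamples of 1-Mb stretches. Background was called raised where it was over 2 times the genome-wide value of the list.

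The 2 lists of each factor differed by less than sampling noise and were counted as 1 sample per factor. No p-value between factors was therefore computed from sites. The replicate numbers come from the titles and pair nothing that the labels describe. Annotation or sequence of GRCz11 was not used here, and the gene table at hand is of another assembly. The planned promoter shares, gene lists, motif counts and 6-mer search were therefore not run, and sites are named by position. Sites were named by a fixed rule, the 10 highest-ranked sites of each factor and the 8 highest-ranked factor-only sites, by the mean percentile of fold enrichment within the lists. The groups, the rule, the long arm of chromosome 4 as the part from 30 Mb, and most alternatives were fixed before the data were examined. The alternatives were a −log10 q of at least 5, a reciprocal overlap of 50%, the 2000 peaks per list with the highest q, and each list left out. Those added afterwards are named as such where they are given. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.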

Results

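Genome occupancy of Drl-FLAG and Blf-FLAG was measured in sorted blood progenitors of zebrafish embryos at 20 hours post fertilisation. The embryos lacked blf and 4 drl genes, and received tagged mRNA, a single one per library by the genotype labels, although the extraction protocol names both. Every comparison of Drl with Blf rests on the genotype labels. The Drl-FLAG lists held 5289 and 5383 peaks, and the Blf-FLAG lists 5482 and 5449 peaks. Median peak widths were 484 and 481 bp for Drl-FLAG and 449.5 and 449 bp for Blf-FLAG. The median fold enrichment given by the authors was 6.52 and 6.34 in the Drl-FLAG lists and 5.33 in both Blf-FLAG lists. Background coverage before scaling, worked out from the peak values, was 0.919 fragments per base in both Drl-FLAG lists and 0.313 in both Blf-FLAG lists. The Drl-FLAG coverage was thus 2.94 times that of Blf-FLAG. The weakest peaks held 8 fragments at the summit in the Drl-FLAG lists and 4 in the Blf-FLAG lists, with medians of 15 and 8. A site missing from the Blf-FLAG lists is therefore known with less certainty than one missing from the Drl-FLAG lists.

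The first comparison was between the 2 lists of each factor. Of the peaks in the first Drl-FLAG list, 84.6% overlapped a peak of the second, and 83.2% did in the other direction. For Blf-FLAG these shares were 72.6% and 72.9%. Random placement gave 0.475% and 0.458%, with a highest value of 0.719% and 0.694% in 100 placements. Agreement extended to single bases. Among overlapping nuclear peaks, 1402 pairs of Drl-FLAG peaks (31.2%) and 1208 pairs of Blf-FLAG peaks (30.3%) had identical starts and ends. Each Drl-FLAG list shared at most 3 such peaks with a Blf-FLAG list. Summits coincided to the base in 56.2% of overlapping Drl-FLAG pairs and 48.4% of overlapping Blf-FLAG pairs. Background coverage differed by 0.024% between the Drl-FLAG lists and by 0.0249% between the Blf-FLAG lists.

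Fragment counts at the summits also differed by less than sampling noise. Independent Poisson counts of equal mean would give a dispersion (squared difference over the sum) of 1. The dispersion was 0.342 over 251 Drl-FLAG summits with a mean of at least 40 fragments (95% bootstrap interval 0.278 to 0.409). It was 0.297 over 127 Blf-FLAG summits (0.206 to 0.422). The 2 lists of a factor were therefore counted as 1 sample, and the differences between Drl-FLAG and Blf-FLAG have no replicate check. In the 3 ways to pair the 4 lists, pairing by factor gave the highest mean overlap, 78.3% against 26.1% and 26.0%. This is the smallest exact permutation p that 3 pairings allow, 0.333, one-sided. Lists that differ by less than sampling noise would give this order whatever the factors.

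**Figure D1:**
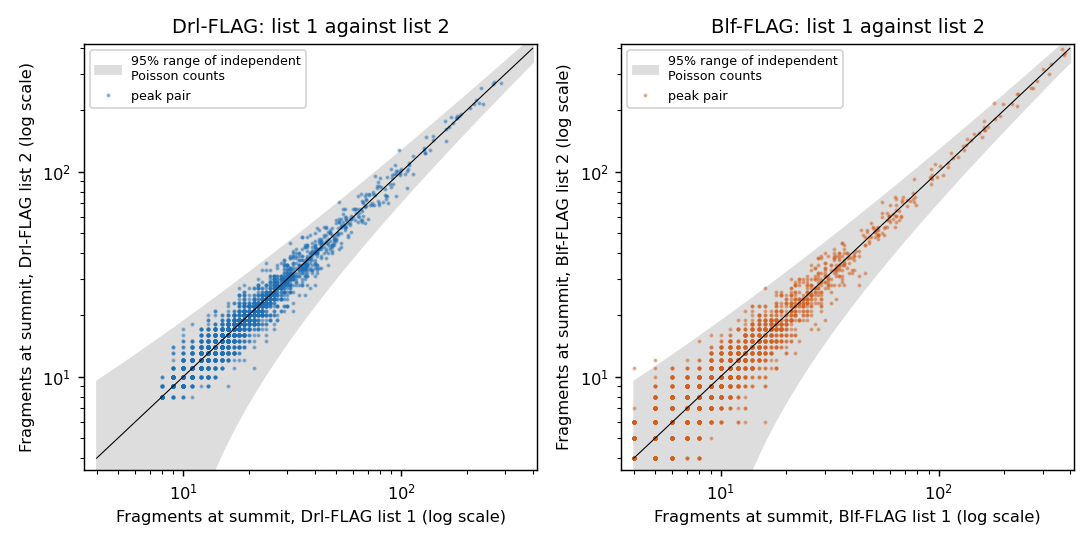
Fragments at the summit in list 1 (horizontal) against list 2 (vertical) for Drl-FLAG (left) and Blf-FLAG (right), both axes logarithmic and shown up to 400 fragments. Each point is a pair of peaks with summits within 100 bp, and the grey band is the 95% range of independent Poisson counts, which the points fill only in its middle (dispersion 0.342 and 0.297 at 40 or more fragments).

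The central comparison asked where Drl and Blf were found together and where apart. The 4 lists formed 11333 nuclear sites, of which 4452 were Drl sites and 3932 Blf sites. Both factors had 1126 sites in common. These made up 25.3% of the Drl sites (95% interval 24.0 to 26.6) and 28.6% of the Blf sites (27.2 to 30.1). Drl-only sites numbered 3091 (69.4% of Drl sites) and Blf-only sites 2561 (65.1% of Blf sites). The Blf-only count was 3871 without Blf-FLAG 1, 3906 without Blf-FLAG 2 and 1082 with a −log10 q of at least 5. At that q the Drl-only count was 2233. Among the 2000 peaks per list with the highest q, 1173 Drl-only and 944 Blf-only sites were found. A further 3963 sites were present in a single list, and 592 fell into other mixtures of lists. Random placement of the Blf sites gave an overlap of 0.419% of Drl sites. Moving each Blf site by 20 to 100 kb, an expectation added after the data were seen, gave 1.21%. The observed overlap was 60.3 times the random and 20.9 times the local value. Neither expectation covers peaks that would arise without either protein, since the labels list no anti-FLAG library from cells without a tagged protein. Such peaks would also count as shared sites.

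Shared sites were the stronger and wider ones. Within Drl-FLAG 1, peaks at shared sites had a median width of 654 bp and peaks at Drl-only sites 476 bp. Within Blf-FLAG 1, the medians were 550 bp at shared and 439 bp at Blf-only sites. Joined over the 4 lists, 70 of the shared sites (6.22%) were wider than 2 kb, compared with 8 Drl-only and 17 Blf-only sites. A shared site joins peaks of both factors and a factor-only site those of a single factor, which favours wide shared sites. Wide peaks also meet the overlap rule of at least 1 bp more easily. The share of Drl sites also called for Blf was 60.4% (55.7 to 65.0) in the highest-ranked decile by fold enrichment and 22.9% (19.1 to 27.1) in the lowest. It did not rise steadily, with a minimum of 14.6% (11.5 to 18.2) in the third decile. The lowest Drl decile by fold was not the weakest by fragments. Its median was 16.5 fragments, against 10 in the second decile and 11 in the third. For Blf sites also called for Drl the share was 65.4% (60.5 to 70.1) in the highest decile and 15.0% (11.6 to 18.9) in the lowest. In the highest decile, 31.9% of Drl sites and 27.2% of Blf sites were still called for that factor only. Control background was raised at 13.2% of Drl-only sites and at 32.0% of shared sites, by the Drl-FLAG values. By the Blf-FLAG values it was raised at 31.3% of Blf-only and 32.7% of shared sites. The labels list 1 input library, and peaks called against the same control would share its chance values. At sites with the lowest control background, chosen after the data were seen, 19.0% of Drl sites and 28.2% of Blf sites were shared.

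**Figure D2:**
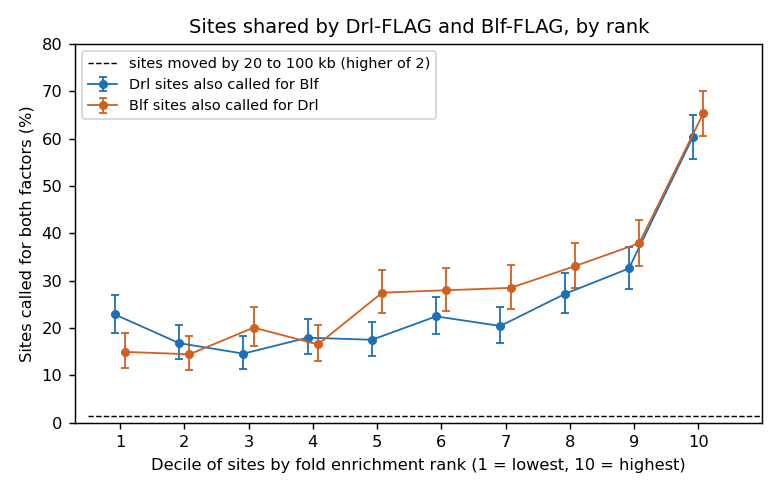
Percentage of Drl sites (blue) and Blf sites (orange) called for both factors, by decile of fold enrichment rank within the factor, with exact 95% binomial intervals as bars. The share is 60.4% and 65.4% in the highest decile and lies above the dashed local expectation (higher value 1.40%) in every decile.

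The 10 highest-ranked Drl sites and the 10 highest-ranked Blf sites were all called for both factors. A high rank did not exclude a raised control background, which was not counted for these sites. The Drl site on chromosome 4 from 42939861 to 42941666 had 163.5 Blf-FLAG fragments at folds of 19.5 and 20.6. The highest Blf site had 97.5 Blf-FLAG fragments at folds of 70.8 and 79.2. More fragments at a lower fold go with a higher background. Positions are those of GRCz11, and the annotation of these positions was not used here. The highest Drl site lay on chromosome 4, from 61299328 to 61300614. The authors' fold enrichment there was 139 and 134 in the Drl-FLAG lists and 16.8 and 13.7 in the Blf-FLAG lists. Second came chromosome 18, 50804311 to 50805161, with 122 and 120 for Drl-FLAG and 16.0 and 12.9 for Blf-FLAG. On chromosome 8, the sites at 38938958 to 38940914 and 45102249 to 45103904 ranked next, with Drl-FLAG folds of 110 and 97.5 and of 96.2 and 94.9. A pair of sites on chromosome 20, 12916868 to 12918526 and 12920145 to 12925113, held the sixth and ninth places. Their Drl-FLAG folds were 76.3 in both lists and 71.4 and 71.6.

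The highest Blf site lay on chromosome 6, from 17723494 to 17724600. Its fold was 70.8 and 79.2 in the Blf-FLAG lists and 45.8 and 59.7 in the Drl-FLAG lists. Chromosome 3, 7279176 to 7279728, followed with 55.3 and 51.1 for Blf-FLAG and 20.1 and 21.7 for Drl-FLAG. Chromosome 5, 68672161 to 68672684, had 45.4 and 53.9 for Blf-FLAG and 19.9 and 18.8 for Drl-FLAG. On chromosome 18 the sites at 30038050 to 30039518, 30047352 to 30049749 and 30049983 to 30050909 took 3 of the 10 places. Drl-FLAG folds at these sites were 50.05 and 47.4, 48.1 and 48.9, and 34.7 in both lists. Folds of the lists rest on different depths and were not compared between factors.

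Factor-only sites reached lower folds. The highest Drl-only site lay on chromosome 25, from 20380663 to 20381932, with folds of 29.7 and 31.1 and a mean of 64.5 fragments at the summit. It was followed by chromosome 22, 38385050 to 38387533, with folds of 23.7 and 27.4 and 54 fragments. Chromosome 9, 54621652 to 54622093, had folds of 23.7 and 26.4 and 53 fragments. The other 5 named Drl-only sites lay on chromosomes 22, 11, 14, 23 and 24, with 41 to 42.5 fragments. The highest Blf-only site lay on chromosome 4, from 21655070 to 21656551, with folds of 21.3 and 25.9 and 30 fragments. Next were chromosome 2, 46516705 to 46517102, with 18.3 and 23.6, and chromosome 25, 37431900 to 37433053, with 24.2 and 17.6. The other 5 named Blf-only sites lay on chromosomes 1, 20 and 16, with 22 to 33 fragments.

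Chromosome 4 was examined on its own because its long arm in zebrafish is rich in repeats and zinc-finger genes. It held 5.93% of Drl sites (5.25 to 6.66) and 8.95% of Blf sites (8.08 to 9.89), while it makes up 5.80% of the span covered by peaks. On the long arm lay 78 Drl-only sites (2.52%, 2.0 to 3.14) and 164 Blf-only sites (6.40%, 5.49 to 7.42). The arm makes up 3.57% of the span. The Blf-only share exceeded the Drl-only share by 3.88 percentage points (2.13 to 6.11 on resampling of 1-Mb stretches). Sites of both factors had 6.39% on the arm (5.04 to 7.99). Blf-only sites were densest between 40 and 44 Mb, with 30 sites against 12 Drl-only sites. Control background was raised at 61.7% of the Blf-only sites on the arm and at 29.3% of those elsewhere. For Drl-only sites these shares were 34.6% and 12.7%. At sites with the lowest control background, chosen after the data were seen, chromosome 4 held 5.57% of Blf sites and 3.73% of Drl sites. At that background the long arm held 2.66% of Blf-only and 1.08% of Drl-only sites, a difference of 1.58 points (0.490 to 2.75).

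**Figure D3:**
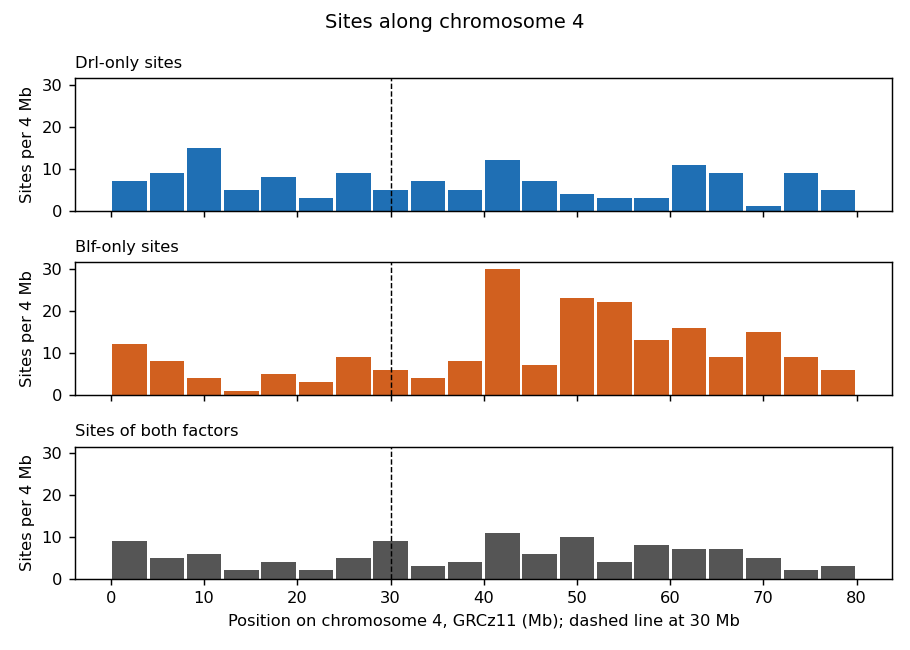
Number of Drl-only (top), Blf-only (middle) and shared (bottom) sites per 4 Mb along chromosome 4 in GRCz11, with a dashed line at 30 Mb, from where the long arm was counted. Blf-only sites reach 30 per 4 Mb beyond that line, where Drl-only sites reach 12.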

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

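Mitochondrial peaks were set aside from the site comparisons and still exceeded the control. The Drl-FLAG lists had 2 such peaks each, covering 14730 bp, with highest folds of 1.58 and 1.57. The Blf-FLAG lists had 7 each, with highest folds of 3.56 and 3.55. No explanation for these peaks was tested.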

How the results depend on the processing

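Of 55 alternative values, 28 were counted as moved, which for shares means outside the interval or range of the value reported. Counts of factor-only sites have no such interval and were judged more loosely. Drl-only counts of 2233 (−log10 q of at least 5) and 3816 (without Drl-FLAG 1) did not count as moved from 3091. The lowest shared part under any alternative was 19.0% of Drl sites. With a reciprocal overlap of 50%, the lists of a factor shared 81.6% (Drl) and 69.6% (Blf) of peaks, and the factors 19.7% of Drl and 22.5% of Blf sites. With a −log10 q of at least 5, the shared part was 20.5% of Drl and 33.7% of Blf sites. Drl-only sites then fell to 2233 and Blf-only sites to 1082, and chromosome 4 held 11.1% of Blf sites. With 2000 peaks per list, 1173 Drl-only and 944 Blf-only sites were left, as shorter lists require. Leaving out 1 list at a time gave shared parts of 23.4% to 28.0% (Drl) and 22.8% to 31.9% (Blf). It gave 3207 to 3816 Drl-only and 2680 to 3906 Blf-only sites. The highest Blf-only values came without Blf-FLAG 1 (3871) and Blf-FLAG 2 (3906), where a single list stood for the factor. Chromosome 4 then held 5.93% to 6.28% of Drl and 8.46% to 8.97% of Blf sites. Alternatives chosen after seeing the data were sites of at least 30 (Drl) or 10 (Blf) fragments, with 65.4% and 36.1% shared (544 and 1538 sites), a −log10 q of at least 5 in the lists of 1 factor only, with 29.9% of Drl and 39.7% of Blf sites shared, and sites at the lowest control background. In the latter, 19.0% of Drl sites were shared, and chromosome 4 held 3.73% of Drl and 5.57% of Blf sites. Lists paired by their number had 59 pair-only sites and lists paired by factor 5652, as lists with common fragments would give in any case. No paired analysis was possible because the 2 lists of a factor were counted as 1 sample and no test across samples was made. Promoter, gene list, motif, 6-mer and repeat-mask alternatives were not run for want of the annotation and sequence used here. The shallower Blf-FLAG coverage limits what can be said of sites missing there.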

Other observations

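Sites of both factors gathered near chromosome ends and in a few dense stretches. The outermost 1 Mb at each end, 3.72% of the span, held 18.5% of shared sites (16.2 to 20.9). It held 16.4% of Blf-only sites (14.9 to 17.9) and 8.96% of Drl-only sites (7.98 to 10.02). The Blf-only share was higher by 7.40 percentage points (5.01 to 9.94, resampling of 1-Mb stretches). At sites with the lowest control background it was 10.5% for Blf-only and 5.08% for Drl-only sites, a difference of 5.42 points (3.32 to 7.67).

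Counting only shared, Drl-only and Blf-only sites, the densest 1-Mb stretch was on chromosome 8 from 34 to 35 Mb, with 32, 13 and 3 of them, against a median of 4 such sites per Mb. Within it, 17 sites lay between 34476311 and 34574084. Control background was raised at 89.6% of its 48 sites. With sites of single lists and other mixtures included, chromosome 15 from 9 to 10 Mb held more (87 against 53). On that stretch of chromosome 15, Blf-only sites prevailed (25, with 9 Drl-only and 9 shared), 22 of the 43 between 9739290 and 9839116. On chromosome 16 from 36 to 37 Mb, Drl-only sites prevailed (20, with 2 Blf-only and 4 shared). On chromosome 18, 16 sites lay between 30025949 and 30088785, and the 26 sites of that Mb had median folds of 27.1 (Drl-FLAG) and 26.6 (Blf-FLAG). Background was raised at 83.7%, 53.8% and 46.2% of the sites in these last 3 stretches.

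Of the tests in the following, that of a stricter threshold on both factors was planned, and all others were chosen after the data were seen. The 2 lists of one factor had peaks at identical positions. A candidate explanation is that both lists contain the same sequenced fragments, since the higher of the 2 dispersions was 0.342. With 2 independently prepared and sequenced libraries and Poisson counts the dispersion would be 1 or more, and the higher upper bound was 0.422. Effects of duplicate removal, and of taking only pairs called in both lists with summits within 100 bp, were not tested. Between 40 and 100 fragments the dispersion was 0.335 (Drl) and 0.231 (Blf). Fixed cutting positions of the transposase would align the summits of the 2 factors too, and these coincided in 2.09% of overlapping pairs, against 52.5% within factors. The dispersions correspond to 65.8% (Drl) and 70.3% (Blf) of fragments in common, as a hypothesis, and how the lists came to share them stays open.

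Most sites were called for only 1 factor. Lower depth of the Drl-FLAG lists is argued against for Blf-only sites, since their coverage was 2.94 times that of Blf-FLAG. For Drl-only sites depth stays open, since 26.3% of them, scaled to the Blf-FLAG coverage, had fewer than the 4 fragments of the weakest Blf-FLAG peaks. The median Drl-only site held 14 fragments before this scaling by 2.94, so many others lay close to that minimum. A stricter threshold on both factors (higher shared part 33.7%) also removed partner peaks and decides nothing. Weak peaks stay open too, since the answer depended on how strictly strong sites were chosen. A −log10 q of at least 5 on 1 factor alone kept 3006 Drl and 1826 Blf sites and left at most 39.7% shared (37.5 to 42.0). The highest deciles, a narrower choice, were mostly shared (60.4% of Drl and 65.4% of Blf sites). At sites of at least 30 (Drl) or 10 (Blf) fragments, 65.4% and 36.1% were shared. Signal to noise of each sample and binding at different places stay open and untested.

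Blf-only sites lay on the long arm of chromosome 4 more often than Drl-only sites. Without the 3 densest stretches of each class the Blf-only share was 4.96% (4.14 to 5.88), above the Drl-only share of 2.08% (1.61 to 2.65). Among sites at the lowest control background it was 2.66% (1.86 to 3.69) against 1.08% (0.693 to 1.60), a difference of 1.58 points (0.490 to 2.75). Raised background is thus argued against as the whole cause of the difference, although both shares then lay below or around the 3.57% of the span that the arm covers. A difference between the proteins and a difference between the 2 samples remain open.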
